A study of Caenorhabditis elegans with 2 samples.

How the data were processed

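Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA to which a protein is attached in fixed tissue. Per the labels, it was applied here to whole young adult Caenorhabditis elegans, 65 h old, from strain RW12210. In this strain a TY1, EGFP and 3xFLAG tag was inserted by CRISPR into the gene hmg-1.2 on chromosome III. The labels' description states that an antibody against GFP was used, while their antibody field names hmg-1.2 itself. The animals had been bleached and starved as larvae to bring them to the same stage. Chromatin was sonicated, with a listed size range of 200 to 800. There was 1 group with 2 samples, which the labels number as biological replicates 1 and 2, so no comparison between conditions could be made. The labels do not say whether the replicates came from separate cultures. Control libraries were not analysed here.

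The deposited peak lists use the ce11 build, per the labels. Its chromosome lengths hold every deposited peak, and the reference genome and Ensembl release 115 annotation used here are of the same assembly. The peak caller and aligner are not given in the sources used here. Each replicate has 2 deposited lists, a ranked list and a thresholded list. There are 4 further lists over both replicates, 2 of them thresholded. The authors' conservative thresholded set was the main peak set, because its name marks it as the stricter one.

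The deposited score of each peak comes from the irreproducible discovery rate (IDR), which measures how well a peak's rank is kept between 2 peak lists, and is capped at 1000. The ranked lists over both replicates also hold a deposited −log10 value of the global IDR. No peak in the conservative set has a score under 830. The lowest −log10 value among ranked peaks with such scores is 2.00, which corresponds to an IDR of 0.01. The deposited signal value of each peak is the authors' own, on a scale that is not stated, and was used here only to describe, rank or filter peaks within 1 list. The peak lists give no read totals, so the depth of both libraries is unknown, and no interval that needs depth is given. A library with fewer reads can yield fewer peaks, so the numbers of peaks per replicate are not compared as biology.

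The summit of each peak was taken from the deposited offset. A gene was called bound when a summit lay from 500 bp upstream to 100 bp downstream of any of its annotated 5′ ends. Where transcripts of a gene start at different places, such an end can lie inside the gene. Of the genes named below, pcyt-2.1, lem-4, alg-1, srh-2, unc-33, unc-31, lit-1, act-4 and aak-2 had their summit within the gene. A summit could bind more than 1 gene. Each summit was also placed in 1 of 7 classes, in the order promoter of a protein-coding gene, 5′ UTR, 3′ UTR, coding exon, intron, non-coding gene and intergenic. Shares were compared with 1000 circular shifts of all summits within their chromosome (two-sided permutation p, smallest possible value 0.001), which keep the spacing of the peaks. Replicate overlap needed at least 1 bp in common and was tested with 1000 circular shifts (one-sided).

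Bound and unbound genes were compared with two-sided Fisher's exact tests against a background of 19973 nuclear protein-coding genes. The 30 gene lists were written from gene names before the data were examined, and cover housekeeping complexes, chromatin and germline functions, signalling, tissue markers and large gene families. Benjamini-Hochberg adjustment was made over the 30 lists, over the biotypes of non-coding genes and over 2080 6-mers. Genes are not replicates, so these tests describe 1 peak set. For most shares the values of the replicates' own thresholded sets stand beside the main value, either as a mean ± SD over 2 replicates or one by one.

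Sequence was read 50 bp either side of promoter summits. Each window was paired with 1 window at the same offset from the 5′ end of a randomly drawn unbound protein-coding gene. Every 6-mer, counted on either strand and at most 1 time per window, was tested with Fisher's exact test. Mean GC content was compared with a permutation test of 100000 resamples.

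The genes named in the text were chosen by a rule fixed before the data were examined. It takes hmg-1.2 and the 20 protein-coding genes with the highest signal among promoter peaks that overlap a thresholded peak of both replicates. It adds up to 4 bound members of each list with the highest signal, and the 5 peaks with the highest signal outside promoter windows. Other features that are named were chosen after their values were seen, and the text says so.

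Before the data were examined, the following alternatives were chosen: the authors' other thresholded set, the peaks with the highest signal, each replicate's own set, narrower and wider promoter windows and assignment to the nearest 5′ end. Others changed the list test and its background, the definition of overlap, the sequence window and the control windows. After the data were seen, a set without peaks within 200 bp of tRNA, snRNA or snoRNA genes was added, and a test of non-coding genes apart from protein-coding promoters. For the SL1 genes, peaks with a passing score that the conservative list lacks were also put back.

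The list test, promoter windows, the promoter shift test, the 6-mer and GC tests and the overlap count were checked on simulated data. The tests of biotypes and chromosomes and the circular shifts of lists and of replicate overlap were not. Simulated lists and background peaks were placed at random. They therefore do not give the rate of false calls for genes or peaks that lie in clusters. With 200 genes given a summit, all 4 lists rich in them were called and 0 of 26 random lists, over 19973 genes. A planted 6-mer ranked 1 of 2080, and 2 of 40 random peak sets passed the shift test at 0.05. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.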

Results

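HMG-1.2 is a C. elegans protein with HMG boxes, a domain that binds and bends DNA. Its genomic positions were mapped in whole young adult animals that carried a GFP-tagged copy at the native locus. The data are 2 replicates of 1 group, and the question is where in the genome the tagged protein was recovered. The authors' conservative set over both replicates held 4149 peaks with a median width of 330 bp, covering 1.09% of the nuclear genome. Replicate 1 alone had 3340 thresholded peaks and replicate 2 had 5333. The sequencing depth behind these lists is unknown.

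Peaks of the replicates lay in the same places far more often than shifted peaks did. Of replicate 1's peaks, 80.4% (2687 of 3340) overlapped a peak of replicate 2, against a mean of 2.99% after circular shifts and a highest value of 3.98% (one-sided permutation p = 0.001, the smallest possible). In the other direction, 49.2% of replicate 2's peaks were overlapped. Of the conservative peaks, 63.6% (2640) overlapped a thresholded peak in both replicates. Across 2536 conservative peaks with a summit within 100 bp in both replicates, the signal ranks had a Spearman rho of 0.593, a description across peaks, which are not independent replicates.

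The peaks gathered at the promoters of protein-coding genes and were scarce in coding sequence. Of the 4149 summits, 1682 (40.5%) lay in a promoter window, against 14.1% after shifts, a ratio of 2.88 (two-sided permutation p = 0.001, the smallest possible). The replicates' own sets gave 39.6% ± 4.99 (SD, n = 2). Coding exons held 2.02% of summits, against 21.7% after shifts, with 4.34% in replicate 1's own set and 1.13% in replicate 2's. Introns held 21.5% against 31.4% (replicates 21.7% ± 2.58, SD, n = 2), and 3′ UTRs 1.64% against 3.01% (replicates 1.91% ± 0.556, SD, n = 2). Summits in non-coding genes (5.50% against 3.58%) and between genes (27.9% against 25.5%) exceeded the shifted shares, with adjusted permutation p of 0.0014 and 0.0035. The replicates' own sets gave 4.91% ± 0.634 and 28.5% ± 1.03 for these (SD, n = 2). The share in 5′ UTRs, 0.819%, did not pass the test against the shifted 0.676% (adjusted permutation p = 0.33). The promoter summits bound 1934 of 19973 protein-coding genes (9.68%), and 341 of the 1682 lay in the windows of more than 1 gene.

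Genes for small structural RNAs stood out above all other gene classes. Among tRNA genes, which encode the adaptors of translation and are transcribed by RNA polymerase III, 476 of 612 (77.8%) were bound, against 9.68% of protein-coding genes. The replicates' own sets gave 73.7% ± 5.78 (SD, n = 2), and the 2074 peaks of highest signal alone gave 42.5%. Of the snRNA genes, which include spliceosomal and spliced leader RNAs, 62 of 129 (48.1%) were bound, with 51.6% ± 6.03 (SD, n = 2) over the replicates. Of the snoRNA genes, whose products guide the modification of ribosomal RNA, 107 of 346 (30.9%) were bound, with 30.3% ± 2.04 (SD, n = 2). The adjusted Fisher's exact p was 3.66e-28 for snRNA and 4.16e-27 for snoRNA genes, and for tRNA genes it fell below the smallest number that could be stored. The odds ratios were 32.6 for tRNA, 8.63 for snRNA and 4.18 for snoRNA genes.

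Summits sat close to the 5′ ends of these short genes. For the 436 peaks in tRNA windows the median summit was at -10.5 bp, with quartiles of -27 and 8 bp. For snRNA genes the median was -57 bp over 60 peaks, and for snoRNA genes -62 bp over 107 peaks. Protein-coding promoters had a broader distribution, with a median of -174.5 bp and quartiles of -290 and -84 bp. All these distances are to annotated 5′ ends, which were not checked against measured transcription starts and may not be alike between classes. The snRNA peaks had a median authors' signal of 662, against 240 over all conservative peaks and 251 for tRNA peaks.

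**Figure D1:**
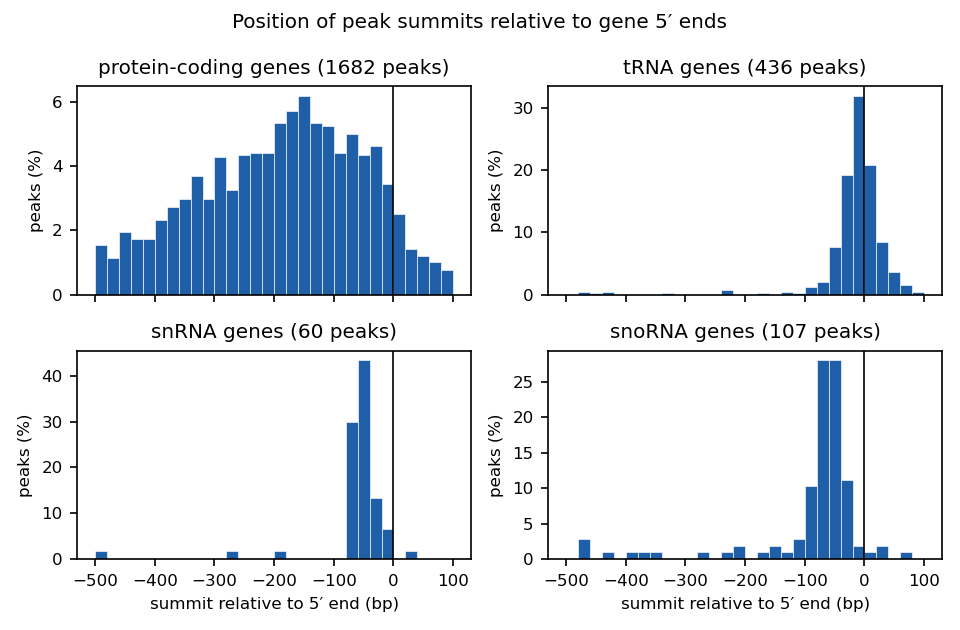
Histograms of the position of peak summits (x axis, bp relative to the annotated 5′ end, negative upstream, in bins of 20 bp) as a percent of the peaks in the windows of each gene class (y axis). Summits at tRNA genes centre near the 5′ end (median -10.5 bp), those at snRNA and snoRNA genes just upstream (medians -57 and -62 bp), and those at protein-coding genes spread over the promoter (median -174.5 bp).

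Within these classes the bound genes were unevenly spread, in groups chosen after their values were seen. The SL2 genes encode the leader RNA that is spliced onto downstream genes of operons. Of the 18 SL2 genes, 17 were bound (94.4%). The 12 SL1 genes, which encode the other spliced leader, lie together on chromosome V, 17118154 to 17132107, where the conservative list holds 0 peaks. The ranked list holds 2 peaks there with a passing score that the conservative list lacks (17122900 to 17123229 and 17129333 to 17129662). With such peaks put back, 2 of the 12 SL1 genes were bound, so the 0 of the listed peaks does not show absence of binding. Of 209 annotated tRNA pseudogenes only 17 were bound (8.13%, 95% Clopper-Pearson interval 4.81% to 12.7%), far below the 77.8% of tRNA genes (Fisher's exact p = 4.38e-75). The 469 tRNA genes whose window overlaps no protein-coding promoter window were bound in 77.6% of cases, and the other 143 in 78.3% (Fisher's exact p = 0.909). Of snRNA genes apart from such windows 38 of 96 (39.6%) were bound, against 48.1% of all snRNA genes. For snoRNA genes these values were 71 of 240 (29.6%) and 30.9%. The X chromosome holds 276 of the 612 tRNA genes, and 80.8% of these were bound, against 75.3% on the autosomes (Fisher's exact p = 0.118). By amino acid, the bound share ran from 60% for methionine and histidine tRNA genes to 96.3% for aspartate among kinds with more than 1 gene. None of 21 kinds passed the test against the rest after adjustment (lowest adjusted Fisher's exact p = 0.336).

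Among the other non-coding classes, miRNA genes were bound slightly more often than protein-coding genes and several classes less often. Of the miRNA genes 36 of 261 (13.8%; replicates 14.8% ± 4.06, SD, n = 2) were bound, an odds ratio of 1.49 (adjusted Fisher's exact p = 0.0433). That call was lost in replicate 2's own set (adjusted exact p = 0.0545), with the peaks of highest signal (0.113) and with a narrow promoter window of 250 bp upstream and 50 bp downstream (6.51% bound, 0.774). It was also lost among miRNA genes apart from protein-coding promoters (12.4% bound, adjusted exact p = 0.244). The piRNA genes, which encode germline small RNAs, were bound in 126 of 15363 cases (0.820%), with a p too small to be stored. All biotype tests treat genes as independent, although neighbouring genes can share a summit. Unlike the list tests, they were not repeated with circular shifts, so their smallest p values may be too low. Pseudogenes (3.10%), unclassified ncRNA genes (7.73%) and antisense RNA genes (1 of 100) also had lower shares than protein-coding genes, with adjusted Fisher's exact p of 3.48e-29, 4.74e-07 and 0.00134. The ncRNA call was lost with the wide window of 1000 bp upstream and 200 bp downstream (12.3% bound, adjusted exact p = 0.48). The lincRNA genes (13 of 194) and rRNA genes (1 of 20) did not pass the test, with adjusted Fisher's exact p of 0.2 and 0.715. The lincRNA share was 6.70%, with 3.61% in replicate 1's own set and 10.3% in replicate 2's. Peaks with a passing score that the lists lack were not put back for these classes.

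**Figure D2:**
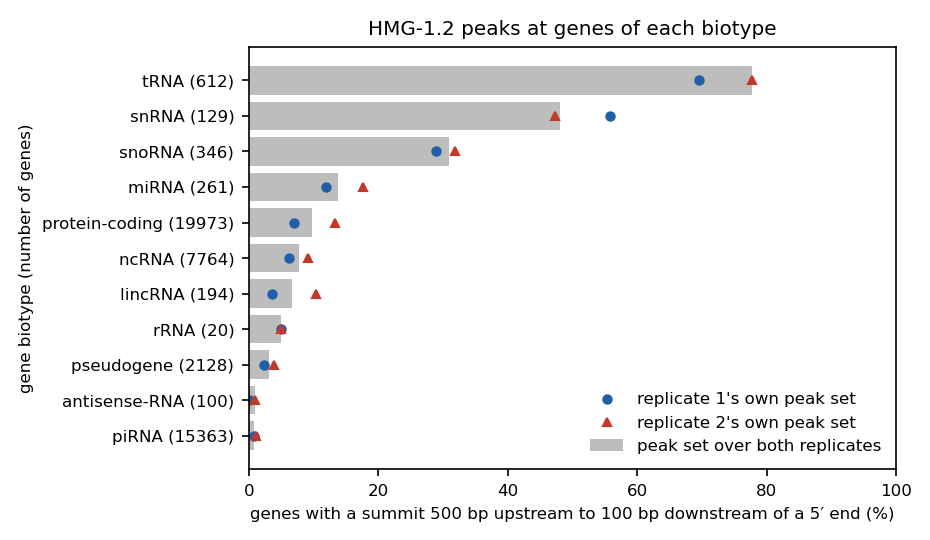
Percent of genes of each biotype (x axis; number of genes in brackets on the y axis) with a peak summit from 500 bp upstream to 100 bp downstream of a 5′ end. Bars show the conservative set over both replicates, circles replicate 1's own set and triangles replicate 2's own set; tRNA genes reach 77.8%, against 9.68% of protein-coding genes.

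The promoter peaks with the highest authors' signal covered genes of varied function. Coordinates are ce11, and signal is in the authors' units. The highest of all 4149 peaks, with a signal of 5688, lay on chromosome IV, 6613323 to 6613700, with its summit at -160 bp from drh-1, which encodes a RIG-I-like helicase of antiviral RNA interference. The peak of rank 6 (4705) lay on chromosome II, 14561669 to 14562050, at -260 bp from mog-4, a helicase gene needed for the switch from sperm to oocytes. The peak of rank 7 (4659; chromosome I, 2084768 to 2085177) was within 200 bp of a small RNA gene. Its summit, at 2084975, lay inside pcyt-2.1 (2078955 to 2085680), at -399 bp from a 5′ end within that gene. The peak of ntl-11, a subunit of the CCR4-NOT deadenylase, had rank 14 (3846; chromosome IV, 15471413 to 15471785). That of hat-1, a histone acetyltransferase gene, had rank 18 (3648; chromosome III, 10407326 to 10407680).

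Further genes among the 20 with the highest signal were lem-4, tag-281, W03F9.1, the complex I gene ndub-8 and the synthetic multivulva gene lin-36. They also included the mRNA cap methyltransferase gene cmtr-1, gpap-1, F44E5.5, the histone methyltransferase gene set-16 and Y48C3A.20. The ribosomal protein genes rpl-7A and rpl-41.2, the kinase gene pig-1, gid-1 and the co-chaperone gene sti-1 completed them. Their ranks ran from 19 to 38 and their summits from -30 bp (gid-1) to -317 bp (rpl-41.2). The summit of lem-4 lay inside the gene, upstream of a 5′ end within it. The peak of cmtr-1 also lay within 200 bp of a small RNA gene.

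The promoter of hmg-1.2 itself was bound in both replicates. Its peak (chromosome III, 6280048 to 6280481) had rank 60 with a signal of 2495 and a summit at -92 bp from the annotated start of the gene at 6280380. Replicate 1 had a summit at -106 bp and replicate 2 at -92 bp. Within its own list the peak had rank 553 of 3340 in replicate 1 (signal 234.6) and rank 15 of 5333 in replicate 2 (signal 2262). A further peak lay between hmg-1.2 and the divergent gene C18F10.7, at 6278470 to 6278790 with a signal of 1806. Its summit, at 6278623, was at -1757 bp from the start of hmg-1.2. It lay in the promoter window of C18F10.7, whose annotated 5′ end is at 6278351. This peak too was present in both replicates, and in replicate 1 its signal (585) exceeded that of the hmg-1.2 promoter peak.

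**Figure D3:**
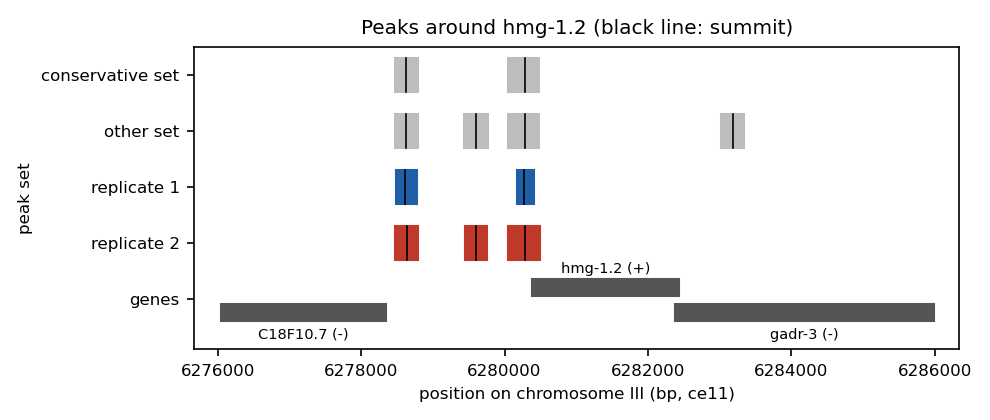
Map of chromosome III around hmg-1.2 (x axis, ce11 position in bp) with the peaks of each set as boxes on separate rows (y axis), black lines at their summits, and genes as dark boxes with their strand. Peaks at 6278470 to 6278790 and at 6280048 to 6280481 in the conservative set have counterparts in both replicates.

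The fixed gene lists differed widely in how often their genes were bound. Of the 30 lists, 13 were bound more often than other protein-coding genes, 4 less often, and 13 did not pass the test. Cytosolic ribosomal protein genes led with 57 of 81 bound (70.4%, against 9.44% of other genes; adjusted Fisher's exact p = 2.52e-38), and 71.6% ± 8.73 (SD, n = 2) over the replicates' own sets. This share depended on the window: it was 19.8% with the narrow window (adjusted exact p = 0.000146) and 48.1% with the nearest 5′ end only (adjusted exact p = 1.47e-20). With the narrow window the cell cycle (35%), germ granule (25.6%) and translation factor (23.8%) lists, among others, had higher shares. Examples were rpl-7A, rpl-41.2, rpl-29 and rpl-3, with ranks of 31, 37, 118 and 127. Chaperone and heat shock genes followed with 29 of 63 (46.0%; adjusted Fisher's exact p = 9.19e-13; replicates 41.3% ± 15.7, SD, n = 2), a share that was 22.2% with the narrow window and 25.4% with the nearest 5′ end only. These included dnj-11, the endoplasmic reticulum Hsp70 gene hsp-3, and hsp-16.2 and hsp-16.41, which share 1 peak on chromosome V (1804959 to 1805243).

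Genes for energy supply and gene expression were bound at intermediate rates. Of the respiratory chain and ATP synthase genes 19 of 51 were bound (37.3%; adjusted Fisher's exact p = 6.12e-07; replicates 40.2% ± 18, SD, n = 2), among them cox-5A, nduf-7, atp-3 and cox-5B. Translation factors were bound in 13 of 42 cases (31.0%; adjusted exact p = 0.000298; replicates 33.3% ± 13.5, SD, n = 2), led by eef-1G and iff-2. Their share was 16.7% with the peaks of highest signal (adjusted exact p = 0.0149). Splicing factors reached 12 of 36 (33.3%; adjusted exact p = 0.000269; replicates 27.8% ± 19.6, SD, n = 2), with snr-4 and prp-18 as examples. The peak of snr-4 lay within 200 bp of a small RNA gene, and prp-18 had no peak in replicate 1's own set. Proteasome subunits reached 10 of 33 (30.3%; adjusted exact p = 0.00203; replicates 31.8% ± 23.6, SD, n = 2), with rpn-9 and rpn-11. Mitochondrial ribosomal protein genes reached 15 of 70 (21.4%; adjusted exact p = 0.00705; replicates 21.4% ± 2.02, SD, n = 2), led by mrps-7 and mrpl-35. With circular shifts in place of Fisher's test, the translation (adjusted permutation p = 0.12), splicing (0.102), proteasome (0.102) and mitochondrial ribosomal (0.147) calls were lost. The splicing and proteasome calls were also lost in replicate 1's own set (adjusted exact p of 0.187 and 0.148) and with the peaks of highest signal (0.629 and 0.207), and the mitochondrial ribosomal call in replicate 2's own set (0.0526) and with the nearest 5′ end only (12.9% bound, 0.284). With the narrow window the proteasome call was lost (15.2% bound, adjusted exact p = 0.092), and the respiratory chain and splicing shares were 23.5% and 19.4%.

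Cell cycle genes were also bound more often, while several germline and chromatin lists passed the test less firmly. Of the cell cycle and DNA replication genes 17 of 40 were bound (42.5%; adjusted Fisher's exact p = 4.08e-07; replicates 40% ± 21.2, SD, n = 2). They included the E2F-family gene efl-1 (rank 44), orc-1 (rank 75), mcm-6 and cdt-1. Germ granule and oogenesis genes were bound in 15 of 39 cases (38.5%; adjusted exact p = 6.62e-06; replicates 38.5% ± 18.1, SD, n = 2), with pos-1, meg-3, mex-1 and mes-3 at the highest signals. That call was lost with the peaks of highest signal (10.3% bound, adjusted exact p = 0.305), and the share was 25.6% with the narrow window. The cell cycle share was 20% with the peaks of highest signal. Smaller counts were found for HMG-box genes (6 of 14, adjusted exact p = 0.00286; replicates 32.1% ± 15.2, SD, n = 2), where hmg-1.2 and hmg-6 led, the latter with a peak within 200 bp of a small RNA gene. Meiosis and synapsis genes had 9 of 34 bound (adjusted exact p = 0.00822; replicates 23.5% ± 16.6, SD, n = 2), led by the synaptonemal complex genes syp-4, with a peak within 200 bp of a small RNA gene, and syp-3. Dosage compensation genes had 4 of 10 bound (adjusted exact p = 0.0214; replicates 40% ± 14.1, SD, n = 2), namely sdc-1, dpy-30, sdc-3 and sdc-2, of which sdc-3 had no peak in replicate 1's own set. Argonaute and RNA interference genes had 8 of 37 bound (adjusted exact p = 0.0406; replicates 20.3% ± 9.56, SD, n = 2), led by alg-1 and mut-15. These last 4 calls, in the order given, were not made in replicate 1's own set (adjusted exact p of 0.145, 0.44, 0.0684 and 0.192) nor with circular shifts (adjusted permutation p of 0.21, 0.197, 0.0899 and 0.634). With the narrow window the HMG-box (21.4% bound, adjusted exact p = 0.092), dosage compensation (10%, 0.624) and Argonaute (10.8%, 0.425) calls were lost. The HMG-box, meiosis and Argonaute calls were lost with the peaks of highest signal (adjusted exact p of 0.325, 0.803 and 0.629). The Argonaute call was also lost with the nearest 5′ end only (0.208) and against only genes with a symbol (0.109, both adjusted exact p).

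The chemoreceptor, F-box and MATH/BTB, C-type lectin and cuticle collagen lists were bound less often than other genes. Of the chemoreceptor genes 6 of 1310 were bound (0.458%; adjusted Fisher's exact p = 1.04e-48; replicates 0.649% ± 0.054, SD, n = 2), including srh-2 and srh-269. F-box and MATH/BTB genes had 12 of 412 bound (2.91%; adjusted exact p = 6.12e-07), with 1.46% in replicate 1's own set and 6.55% in replicate 2's. C-type lectin genes had 5 of 240 bound (2.08%; adjusted exact p = 1.73e-05; replicates 2.5% ± 1.18, SD, n = 2) and cuticle collagen genes 3 of 175 (1.71%; adjusted exact p = 0.000159; replicates 2.57% ± 0.404, SD, n = 2). The members with the highest signal were fbxa-145, clec-57 and col-151. The peaks of srh-269 and clec-57 lay within 200 bp of a small RNA gene. With circular shifts in place of Fisher's test, the calls for F-box, lectin and collagen genes were lost (adjusted permutation p of 0.102, 0.157 and 0.165). Because whole animals of 1 stage were used, binding in few cells or at other stages could be missed. A low share therefore does not show that HMG-1.2 avoids these genes.

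The remaining lists did not pass the test. Histone genes had 13 of 75 bound (17.3%; adjusted Fisher's exact p = 0.0523), with his-68 and htz-1 as examples. This list passed as bound more often in the authors' other thresholded set (22.7%; adjusted exact p = 0.0452), with the narrow window (14.7%; 0.0115), with the wide window (29.3%; 0.00039) and without peaks near small RNA genes (17.3%; 0.0416). It did not pass in replicate 1's own set (8%; adjusted exact p = 0.776) or replicate 2's (20%; 0.14). Nor did it pass with the peaks of highest signal (8%; adjusted exact p = 0.506) or the nearest 5′ end only (10.7%; 0.521). Against only genes with a symbol (adjusted exact p = 0.212) and with circular shifts (adjusted permutation p = 0.197) the histone list also failed to pass. Wnt signalling genes had 5 of 30 bound, among them unc-37, the β-catenin gene sys-1, dsh-2 and lit-1, and passed with the peaks of highest signal (16.7%; adjusted exact p = 0.0451). No major sperm protein gene was bound (0 of 31, adjusted exact p = 0.108), and that list passed as bound less often in the other thresholded set (adjusted exact p = 0.0298) and with the wide window (0.043), also at 0. None of 6 Hox genes was bound. None of 21 hypodermis and seam genes was bound in the conservative set or replicate 1's own set, against 9.52% in replicate 2's own set and 4.76% in the other thresholded set. The tissue lists gave 2 of 26 for intestine (fat-6 and vit-6), 2 of 36 for muscle (unc-112 and act-4) and 3 of 31 for neurons (unc-33, unc-31 and maco-1). The peak of unc-31 lay within 200 bp of a small RNA gene. Of the genes named in this paragraph, lit-1, vit-6, act-4, maco-1, aak-2 and smk-1 had no peak in replicate 1's own set. The intestine share was 7.69%, with 3.85% in replicate 1's own set and 11.5% in replicate 2's. The muscle share was 5.56%, with 2.78% in replicate 1's own set and 19.4% in replicate 2's, and the neuron share 9.68%, with 6.45% and 16.1%. Gonad and vulva development genes had 2 of 25 bound (sys-1 and lin-3), and insulin signalling and longevity genes 3 of 22 (aak-2, sir-2.1 and smk-1), a share of 13.6%, with 4.55% and 22.7% in the replicates' own sets. Homeobox ceh genes had 7 of 63, and cytochrome P450 and UDP-glucuronosyltransferase genes 8 of 141 (5.67%, with 2.84% and 10.6% in the replicates' own sets). Nuclear hormone receptors had 18 of 269 (6.69%, with 5.58% and 15.2%). Against only genes with a symbol of their own, these receptors and the cytochrome P450 list passed as bound less often (adjusted exact p of 0.0153 and 0.0407).

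**Figure D4:**
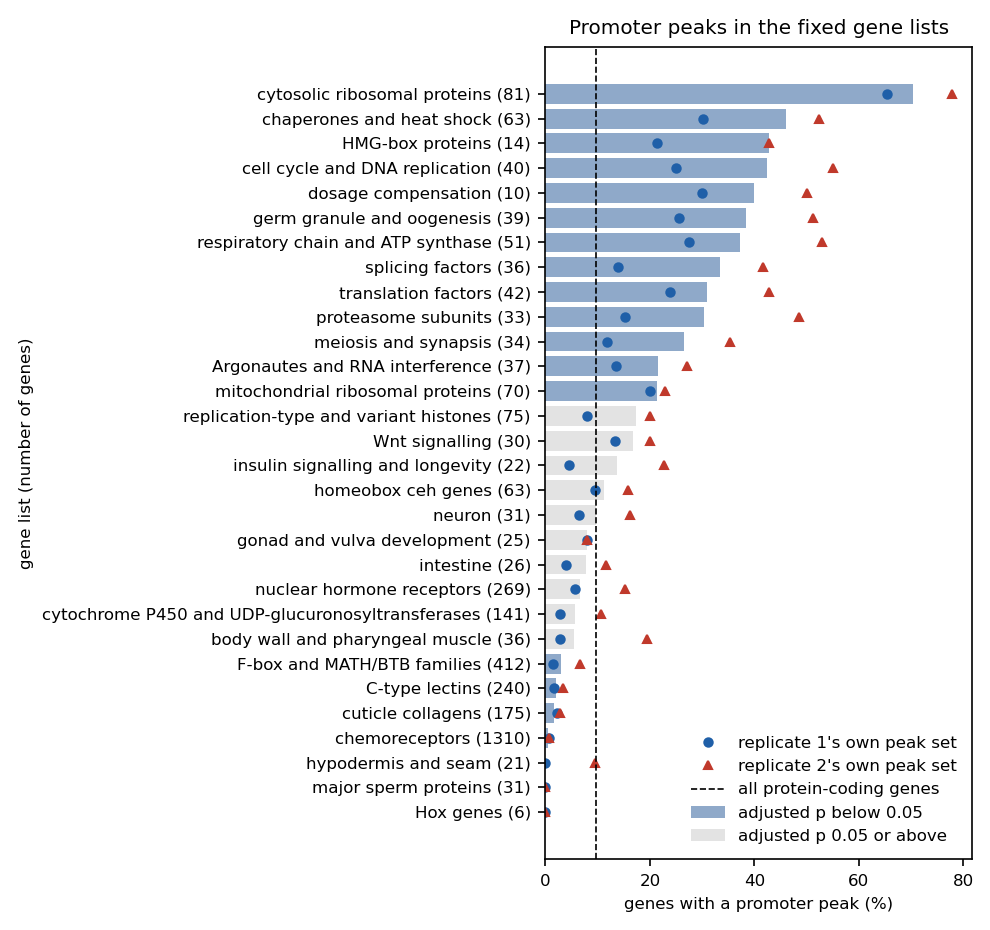
Percent of genes with a promoter peak (x axis) in each of the 30 fixed lists (y axis, number of genes in brackets). Bars show the conservative set, darker where the adjusted p is below 0.05; circles and triangles show the replicates' own sets, and the dashed line marks all protein-coding genes (9.68%). Ribosomal protein genes reach 70.4% and chemoreceptors 0.458%.

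Bound protein-coding genes were scarcer on the X chromosome. On X 199 of 2731 genes were bound (7.29%), against 1735 of 17242 on the autosomes (10.1%), an odds ratio of 0.702 (Fisher's exact p = 2.96e-06). Both replicates' own sets gave odds ratios below 1, 0.634 for replicate 1 and 0.71 for replicate 2. Peaks of all kinds were densest on chromosome III, with 59.7 per Mb, and least dense on V (29.3) and X (33.7). Within the autosomes, 733 of 6568 genes in the central part (1 of 3 equal lengths) were bound (11.2%), against 1002 of 10674 in the outer parts (9.39%), an odds ratio of 1.21 (Fisher's exact p = 0.000192). That difference was not found in replicate 1's own set (odds ratio 1.03, Fisher's exact p = 0.65). It also did not pass with the peaks of highest signal (1.07, Fisher's exact p = 0.365) or the narrow window (1.1, Fisher's exact p = 0.141).

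Promoter summits were rich in G and C. Windows of 50 bp either side of the summit had a mean GC content of 47.6% ± 7.53 (SD over 1682 windows), against 34.6% ± 8.27 at the same offsets in unbound promoters. The difference was 13.0 percentage points (permutation p = 1e-05, the smallest possible), and the replicates' own sets gave 12.8 and 12.6.

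A single sequence family led the 6-mers. ACGCAG (CTGCGT on the other strand) was present at 488 of 1682 promoter summits (29.0%), against 31 of 1682 control windows (1.84%; adjusted Fisher's exact p = 1.97e-119). The overlapping 6-mers GACGCA (28.4% against 2.14%), AGACGC (27% against 1.78%) and CGCAGA (27.7% against 2.2%) came close behind. CGTCTC (30.9% against 3.15%) and the repeats GAGAGA (34.7% against 6.66%) and AGAGAG (28.4% against 5.53%) were also common. Around ACGCAG in 466 windows, the longest unbroken run of bases that were each found in at least 50% of windows was AGAGACGCAGA. Past 1 variable base, A followed in 61.4% of windows. Of 2080 6-mers, 630 were more frequent at summits and 523 less frequent. The less frequent ones with the lowest p included TAAAAA (12.5% against 35.3%) and AAAATT (17.5% against 40.8%). With controls matched on GC content these were no longer less frequent (13.1% against 11.5% and 18.2% against 17.4%; adjusted Fisher's exact p of 0.322 and 0.726). With these controls 375 6-mers were less frequent, 151 of them among the 523, and 233 were more frequent, 191 of them among the 630. ACGCAG then stood at 28.8% against 5.60% (adjusted Fisher's exact p = 8.38e-70).

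Of the 10 peaks with the highest signal, several lay outside promoter windows. The 5 highest of these were all classed as intergenic. The peak of rank 2 (signal 5570) lay on chromosome III, 11036122 to 11036510, with its summit 229 bp past the 3′ end of Y48A6B.9. The peaks of rank 3 (5548) and rank 4 (5305) lay on chromosome IV, with summits on either side of the pseudogene WBGene00023323. They spanned 4725362 to 4725825 and 4727808 to 4728262, and the rank 4 peak overlapped the pseudogene. Their summits were 368 bp from its 3′ end and 69 bp from its 5′ end. The rank 3 summit was nearer to 2 other genes. It was 142 bp upstream of the ncRNA gene WBGene00195021, which that peak covers, and 283 bp past the 3′ end of K08F11.1. The peak of rank 5 (5102; chromosome IV, 10697568 to 10697956) was 619 bp from the 3′ end of R102.11. The peak of rank 8 (4343; chromosome I, 12065242 to 12065681) was 425 bp upstream of the tRNA gene WBGene00014411 and 503 bp from the 3′ end of F58D5.2.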

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

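No group was large enough for a search for outlying samples, and 1 group allows no difference between groups. One signal lies in data that the comparisons above did not use. The ranked list over both replicates holds 24 peaks whose score is at least that of the lowest listed conservative peak and that the conservative list lacks. They are spread over 6 chromosomes, and several lie close together, such as 3 between positions 14779887 and 14781599 on chromosome IV and 2 among the SL1 genes on chromosome V. Their authors' signal reaches 1088 (chromosome IV, 3368689 to 3368954). The other set over both replicates lacks 63 such peaks, replicate 1's list 19 and replicate 2's list 69. No explanation was tested.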

How the results depend on the processing

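Of the settings named here, the removal of peaks near small RNA genes, the test of non-coding genes apart from protein-coding promoters and the return of unlisted peaks at SL1 genes were chosen after seeing the data. The share at promoters, the number of feature classes that differed, the replicate overlap, the GC difference and the lower share on X kept their direction and their side of the threshold under each alternative run for them. The promoter share ran from 26.6% to 52.1% and the X odds ratio from 0.602 to 0.813. With the peaks of highest signal the set had 2074 peaks by construction, and 8 lists were bound more often. With circular shifts 5 lists were bound more often and 1 less often. Shifted summits bound a mean of 593 genes against 1934, and the test divided each list's excess by the number of bound genes. Without replicate 1 or without replicate 2 the lists bound more often numbered 7 to 12, and the odds ratio of chromosome centres was 1.03 to 1.24. That odds ratio was also 1.07 with the peaks of highest signal (Fisher's exact p = 0.365) and 1.1 with the narrow promoter window (Fisher's exact p = 0.141). With controls matched on GC content 233 6-mers were more frequent. For these the cause was not tested. With the unlisted peaks returned, 2 of 12 SL1 genes were bound, against 0. Of 394 values of single lists, biotypes and feature classes under an alternative, 349 stayed on the same side of the threshold, 36 lost a call and 9 gained one. Among values called in either setting, 0 turned round. Values called in neither counted as the same side, whatever their direction. Nuclear hormone receptors, for example, had 6.69% bound against 9.72% of other genes in the main set. In replicate 2's own set they had 15.2%, where 13.3% of all protein-coding genes were bound. Of the 17 called lists, 5 were called under all alternatives: cytosolic ribosomal proteins, chaperones, respiratory chain, cell cycle and chemoreceptors. The unknown depth limits any reading of unbound genes, since replicate 1 has fewer peaks.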

Other observations

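The tests of peak classes by 6-mer were chosen after the results they measure, or related ones, were seen. The leading 6-mer was not confined to summits in promoter windows. Summits outside them were not compared with control windows, so enrichment there was not tested. Some may still lie near promoters, since the wide promoter window held 52.1% of all summits against 40.5%. ACGCAG was present at 36.9% of 1963 summits outside promoter windows and away from small RNA genes (95% Clopper-Pearson interval 34.8% to 39.1%), and at 30.1% of 1587 promoter summits away from them (27.8% to 32.4%). At the 436 summits in tRNA windows it was present in 10.1% (7.43% to 13.3%). Among 12 lists with at least 10 bound genes, none passed the test against other bound genes for how often its peaks held ACGCAG, after adjustment. F-box and MATH/BTB genes had 8 of 12 (adjusted Fisher's exact p = 0.087) and germ granule and oogenesis genes 1 of 15 (adjusted Fisher's exact p = 0.328).

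The tRNA genes form the clearest pattern, and 2 explanations were tested. Reads shared between identical copies do not account for it alone. Genes with a sequence found in no other tRNA gene were bound in 56.6% of cases against 84.2% of genes with identical copies, a ratio of 0.673. The lower share (Fisher's exact p = 4.09e-11) leaves a contribution open. Reads shared between nearly identical copies were not tested, because only exact identity of the gene sequence separated these groups. The ratio of 0.105 between tRNA pseudogenes and genes argues against tRNA-like sequence alone. Transcription by RNA polymerase III stays open. Of the SL2 genes, which RNA polymerase II transcribes, 17 of 18 were bound, so binding was not confined to genes of polymerase III, but this does not exclude that polymerase as the cause at tRNA genes. The SL1 genes decide nothing here, because peaks among them are missing from the thresholded lists.

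The ribosomal protein genes were the most often bound list with the main promoter window, though not with the narrow one (19.8%, against 35% of cell cycle genes). Without peaks near tRNA, snRNA and snoRNA genes their bound share was 69.1% against 70.4%, a ratio of 0.982, which argues against small RNA genes next to or inside them as the cause. Crowded promoters are argued against as the sole cause. Genes matched on the number of neighbouring 5′ ends within 1000 bp gave a mean of 13.2 and at most 27 bound genes in 10000 draws, against 57 observed (permutation p = 0.0001, the smallest possible). With the nearest 5′ end only, however, the share fell from 70.4% to 48.1%, and that of all protein-coding genes from 9.68% to 8.05%. Some of these ribosomal protein genes were thus called bound from summits nearer to another gene. What stays open is that strongly transcribed, open promoters may give signal in any GFP pull-down, which cannot be told apart from binding of HMG-1.2 because no pull-down without the tagged protein was analysed here. The same limit applies to the tRNA genes and to the other lists bound more often. No biological explanation was tested.

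The lower share of bound genes on the X chromosome was weighed against 2 explanations, wider spacing of genes and seldom bound families. Autosomal genes matched on neighbouring 5′ ends gave a mean of 269.6 and at least 219 bound genes in 10000 draws, against 199 on X (permutation p = 0.0001, the smallest possible). This argues against wider spacing. Without the 4 lists bound less often in these same data, the odds ratio was 0.641 (Fisher's exact p = 2.8e-09). The removal left 2647 of 2731 X genes but only 15189 of 17242 autosomal genes. It could therefore only lower the odds ratio and is no independent test. Being scarcer on X, those families do not account for its lower share. The tRNA genes on X did not show a lower share. A scarcity of germline-expressed genes on X may contribute and was not tested.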
